A study of Homo sapiens with 12 samples.

How the data were processed

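Libraries of total RNA from HaCaT cells, 3 in each of 4 groups, were taken as the labels group them: wild type and VDR knockout, untreated or treated for 8 h with 1,25(OH)2D3. The hormone's dose, the vehicle and the number of knockout clones are not given in the sources used here. The authors deposited a table of raw read counts per gene and library, with 16271 human Ensembl gene IDs and their symbols. A second deposited table holds CPM (counts per 1e6 counts of the library), which equal each count divided by the total of its column to within 0.005. Deposited enrichment tables hold a p-value and an adjusted p-value per gene ontology term, per the file headers, and other values, the number of listed genes in the term (Count). Of these, 7 were used and 5 were not, 4 of them because their groups differ in both genotype and treatment. Which group was higher in each table was settled by matching its listed genes to the fold changes, of which 99.4 to 100% had 1 sign. Per the submitters' processing notes, reads were aligned with BWA 0.5.9 and the genome build was mm9, a mouse build. The gene IDs are human, so the build and annotation actually used, and the counting tool, are not given in the sources used here. Positions are those of the gene IDs in GENCODE v29 on GRCh38, which held 15524 of the IDs and lacked 747, and gene types come from there. Genes are named by the deposited symbols, some of which are old, and the current symbol is given beside only some of these.

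Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling (factors 0.95 to 1.057), the filterByExpr filter, which left 14676 genes and set aside 1595, and the robust quasi-likelihood F test on all 12 libraries (common dispersion 0.0117). P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p below 0.05 were called, with no minimum fold. Values after ± beside a log2 fold change are approximate standard errors (SE), with n = 3 per group. Each was derived as the size of the log2 fold change divided by the square root of its quasi-likelihood F statistic. They are least reliable for genes with few counts, where the fold change depends on the prior count. Values after ± beside CPM are standard deviations. CPM printed for single genes were scaled by TMM. There were 5 comparisons: treatment in each genotype, genotype in each treatment, and the difference of the treatment responses. Of the genes tested, 808 had counts equal to those of another gene in every library, and 18 had at most 2 counts in 1 library and at least 50 in another of the same group. A group with no counts was taken at a floor of 3 counts over the group for a lower bound on the fold, and a group with 1 to 3 counts gives a ratio with a 95% exact binomial (Clopper-Pearson) interval. Both cover counting error only.

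The comparisons, the alternatives, the rule for named genes and the gene lists were fixed before the data were examined. The rule names VDR, CYP24A1 and CYP27B1 in each comparison. It also names the 10 genes with the largest rise and the 10 with the largest fall among those called with a mean of at least 1 CPM in a compared group and no overlap between the replicates. For the difference of responses it names 5 each way. For treatment in wild type cells it adds the 8 lncRNA genes each way with the smallest adjusted p, and from each list the 2 to 4 members with the smallest adjusted p. Some genes that meet the rule are not reported here. The lists cover classic vitamin D targets, vitamin D metabolism, receptor and cofactors, differentiation, basal keratinocyte and hemidesmosome genes, simple epithelial and activation keratins, the lipid barrier, antimicrobial genes, inflammatory cytokines and NF-kB targets, the type I interferon response, antigen presentation, S phase, G2/M, Wnt, hedgehog, TGF-beta and YAP targets, epithelial to mesenchymal markers, EGFR ligands and immediate early genes, cholesterol synthesis, hypoxia and glycolysis, ATF4 and unfolded protein stress, p53 targets, markers of other cell types and known regulatory lncRNAs. A list of mitochondrially encoded transcripts had 0 genes in the table and gave no result. The 23 tested lists were compared with other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside the same test with an estimated correlation and fry, adjusted over the lists within a comparison. An lncRNA gene is one of that type in GENCODE v29, of which the table held 1877.

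The alternatives were other scalings (DESeq2's size factors, library size alone), no filter on low counts or a stricter one, DESeq2 1.42.0, limma on the log2 of the deposited CPM with a pseudocount of 1, stricter thresholds (adjusted p below 0.01, at least 2-fold), the compared groups alone, the replicate number as a block, each replicate left out in turn, and lncRNA genes by symbol. Removal of a trend with gene span, joint removal of 2 libraries, and further checks of the lists were added after the data were seen. On simulated counts with the real means, dispersions and library sizes and 200 changed genes, edgeR called 183 genes, 9 of them false, and recovered 73.1% of genes changed 1.5-fold, 89.6% at 2-fold and 98.5% at 4-fold. DESeq2 called 195 genes, 22 of them false. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.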

Results

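Total RNA of HaCaT cells, an immortalised line of human keratinocytes, was sequenced in 12 libraries. The labels give wild type cells and cells with a knockout of VDR, the gene of the nuclear receptor for vitamin D, each untreated or treated for 8 h with 1,25(OH)2D3, the active hormone form of vitamin D. Each of the 4 groups had 3 libraries. Total counts per library (M, 1e6 counts) were 11.49 to 12.21 M in untreated wild type cells and 13.13 to 13.89 M in treated ones. In knockout cells they were 12.61 to 15.99 M untreated and 11.83 to 12.77 M treated. The series title names long noncoding RNA (lncRNA) genes raised by the hormone. The 4 groups allow the response to be compared between wild type cells and cells labelled as VDR knockout.

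The first principal component, with 75% of the variance of log2 CPM (counts per 1e6 counts of the library), separated the genotypes, and the second, with 7.1%, separated treated from untreated libraries within each genotype, in opposite directions. Untreated wild type replicate 3 stood apart, at -32.5 on the first component against -54.3 and -55.7 for the other libraries of its group. On the second component it was at -32.4, against -10.8 and -20.7 for those libraries. Between libraries of a group, Spearman's rho across genes, which are not independent replicates, was 0.9842 to 0.9957.

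**Figure D1:**
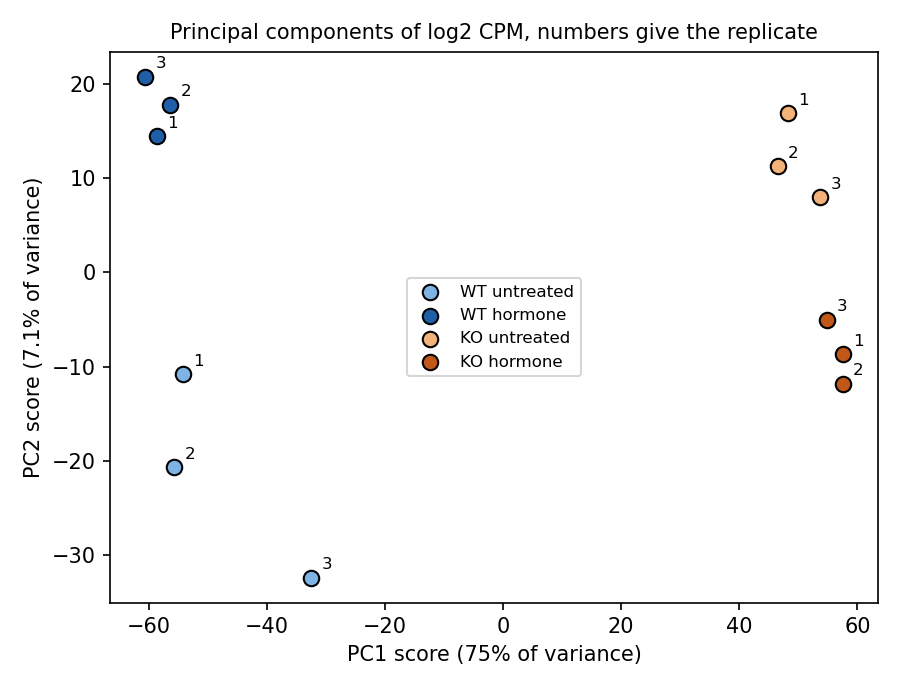
Scores of the 12 libraries on the first (75% of variance) and second (7.1%) principal components of log2 CPM, coloured by group, with the replicate number beside each point. Knockout libraries lie at 46.5 to 57.5 on the first component, and wild type libraries at -60.6 to -54.3 except untreated replicate 3 at -32.5.

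CYP24A1, which encodes the enzyme that inactivates the hormone and is a textbook target of its receptor, rose 34.9-fold in treated wild type cells, from 48.0 ± 2.88 to 1676 ± 61.1 CPM (SD, n = 3). In knockout cells it stood at 16.9 ± 4.83 CPM untreated and 12.2 ± 0.232 CPM treated. The change in knockout cells did not pass the test (log2 fold change -0.47 ± 0.16 SE, adjusted p = 0.106, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). RNA of VDR was counted in every library, at 103.3 ± 3.81 CPM in untreated and 71.0 ± 3.62 CPM in treated wild type cells, and at 77.6 ± 4.07 and 82.8 ± 3.02 CPM in knockout cells. These counts do not measure the protein, and the place and kind of the edit are not given in the sources used here. VDR fell in treated wild type cells (log2 fold change -0.54 ± 0.07, adjusted p = 7.74e-05) and did not pass in knockout cells (0.09 ± 0.07, adjusted p = 0.452), a difference of 0.64 ± 0.10 (adjusted p = 0.000371). CYP27B1, which encodes the enzyme that makes the hormone, did not pass with treatment in wild type cells (-0.15 ± 0.16, adjusted p = 0.528) or knockout cells (-0.06 ± 0.18, adjusted p = 0.885). It was lower in untreated knockout than wild type cells, at 4.44 against 9.83 CPM (-1.14 ± 0.17, adjusted p = 1.13e-05). CYP24A1 (chromosome 20, 54153449 to 54173973), VDR (chromosome 12, 47841537 to 47943048) and CYP27B1 (chromosome 12, 57762334 to 57768986) are placed on GRCh38.

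**Figure D2:**
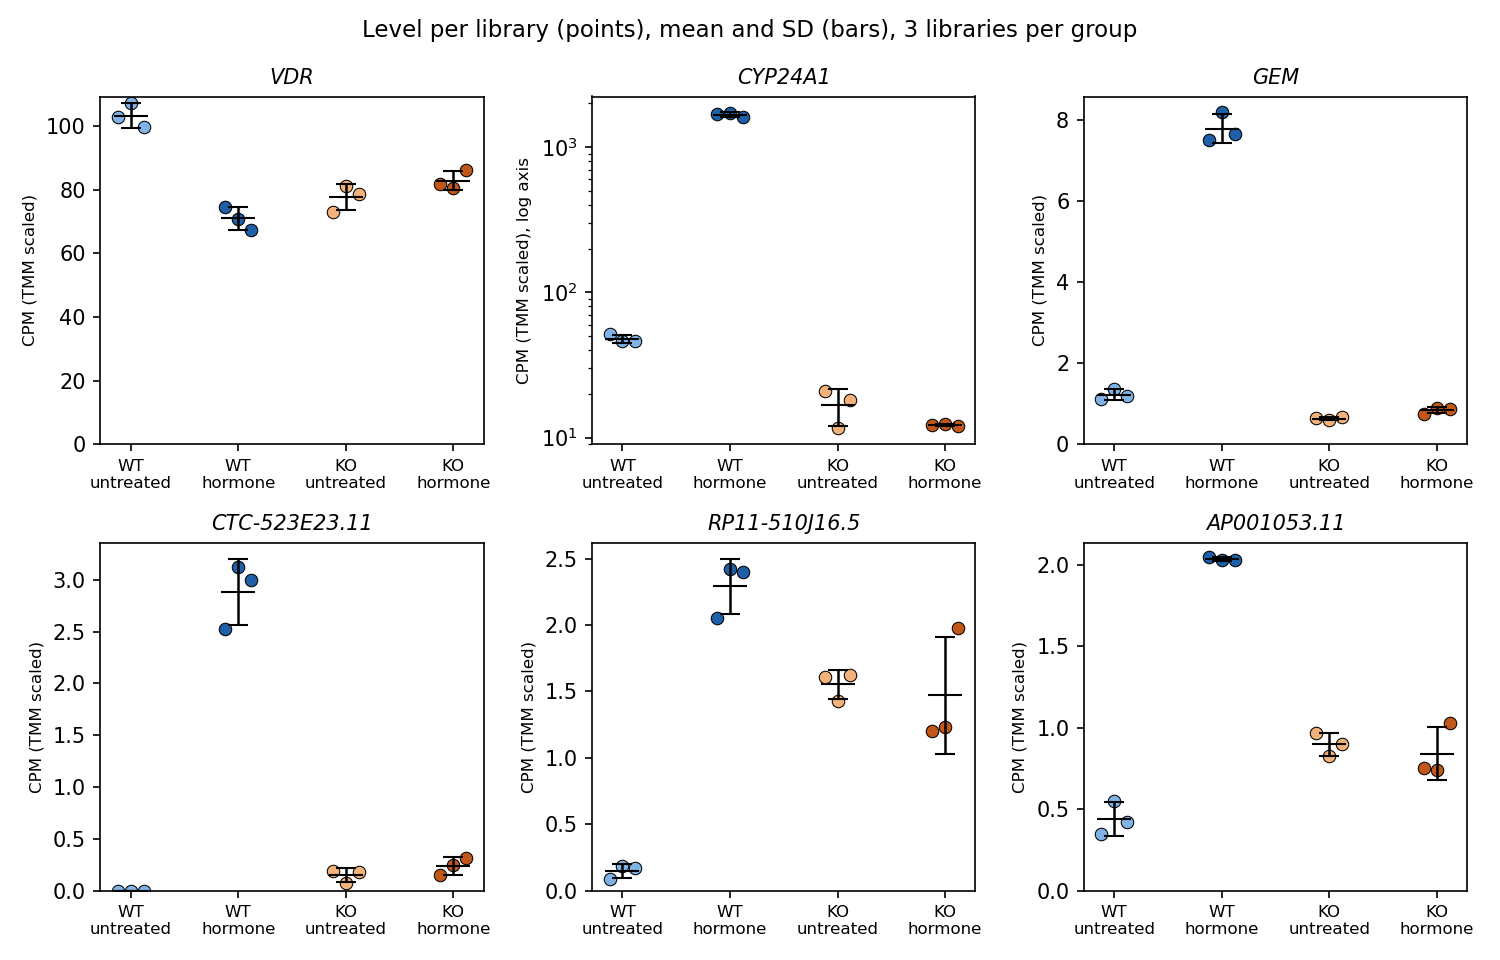
CPM after composition scaling of VDR, CYP24A1 (log axis), GEM and 3 lncRNA genes in each library (points), with the mean and SD of the 3 libraries of each group (bars). CYP24A1 averaged 1676 CPM in treated wild type cells and 12.2 CPM in treated knockout cells.

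Which genes the hormone changed in wild type cells was the first comparison. Besides CYP24A1, the largest rises among genes chosen by the rule were in GEM, a small GTPase (6.32-fold, log2 fold change 2.66 ± 0.19, adjusted p = 3.32e-07), and 3 noncoding genes described further on. C2orf54 (1.97 ± 0.29), the adhesion molecule gene CEACAM6 (1.88 ± 0.41), DHRS9, a short-chain dehydrogenase of retinoid metabolism (1.80 ± 0.22), PRR5L (1.78 ± 0.19) and the semaphorin gene SEMA6D (1.69 ± 0.21) rose as well. IL8, now CXCL8, a chemokine that attracts neutrophils, fell from 18.8 ± 6.13 to 4.88 ± 0.480 CPM (log2 fold change -1.95 ± 0.20, adjusted p = 2.93e-05). ANKRD1 (-1.54 ± 0.23) and the G protein subunit gene GNG11 (-1.48 ± 0.41) fell, as did the counts at the small RNA genes MIR29A (-1.64 ± 0.34), MIR29B1 (-1.49 ± 0.34) and SNORA17 (-1.50 ± 0.38). The largest fall carried a doubt about the origin of the reads, since RPS26P8 (-3.69 ± 0.73) is a pseudogene. EPN2 (-3.31 ± 0.89) followed. Among untreated knockout libraries, used here only for the estimate of spread, it varied from 6.61 to 73.1 CPM. AF274855.1 (-1.69 ± 0.41) and RP3-390M24.1 (-1.47 ± 0.35) complete the genes of the rule. Of 14676 genes tested, 1688 rose and 1914 fell (edgeR quasi-likelihood, adjusted p below 0.05), 72 and 62 of them at least 2-fold. Without treated wild type replicate 1 the counts were 1119 and 1273, and without replicate 3 they were 1010 and 1102. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries.

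The fixed gene lists group this response. The counts given are over all genes tested, and those adjusted over the list alone were equal unless given. Of 23 classic vitamin D targets tested, 11 rose, 2 fell and 10 did not pass (12 and 2 adjusted over the list alone). CYP24A1, DUSP10, a phosphatase of stress kinases (1.18 ± 0.09), CLMN (0.79 ± 0.07) and EFTUD1 (0.81 ± 0.09) had the smallest adjusted p. The list stood higher than other genes (camera adjusted p = 2.58e-05, and adjusted p = 0.0152 with an estimated correlation). Of 21 antigen presentation genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone), among them the peptide-loading genes TAPBP (0.64 ± 0.08), TAP2 (0.54 ± 0.08) and TAP1 (0.61 ± 0.13). Camera called this list higher (adjusted p = 0.0198), but not with an estimated correlation (adjusted p = 0.57). Without treated wild type replicate 1 or replicate 2, 5 of its members rose, and without replicate 2, 1 fell. No other list passed camera in this comparison.

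Of 14 genes of vitamin D metabolism, receptor and cofactors, 3 rose and 4 fell (4 and 4 adjusted over the list alone), with HR, a corepressor (0.72 ± 0.10), and PDIA3 (0.72 ± 0.11) higher, and 2 fell without treated wild type replicate 3. Among 24 inflammatory cytokines and NF-kB targets, 4 rose and 9 fell (5 and 9 adjusted over the list alone), with IL1B (-0.94 ± 0.14), IL18 (-0.46 ± 0.07) and CXCL1 (-0.63 ± 0.10) lower beside IL8. Among 36 type I interferon response genes, 1 rose and 8 fell, with IFIT2 (-0.41 ± 0.09) and IFIT3 (-0.36 ± 0.08) lower, and without treated wild type replicate 1, 2 or 3, 5, 4 and 5 fell. Of that list 2 rose without untreated replicate 2 and 0 without untreated replicate 1 or treated replicate 1 or 3. Of 21 ATF4 and unfolded protein stress genes, 4 rose and 5 fell (6 and 8 adjusted over the list alone). The risen members included the endoplasmic reticulum chaperones HSP90B1 (0.78 ± 0.09), PDIA4 (0.62 ± 0.09) and CALR (0.67 ± 0.12), while PSAT1, an enzyme of serine synthesis, fell (-0.45 ± 0.07). Without untreated wild type replicate 2, 7 of that list rose, and without untreated replicate 1 or treated replicate 3, 3 fell. Of 17 epithelial to mesenchymal markers, 6 rose and 1 fell (7 and 2 adjusted over the list alone), and the risen ones, FN1 (0.73 ± 0.11), CDH1 (0.65 ± 0.10), EPCAM (0.54 ± 0.11) and ESRP2 (0.41 ± 0.08), held both the mesenchymal matrix gene FN1 and 3 epithelial genes, while 2 fell without untreated replicate 2. Of 20 EGFR ligands and immediate early genes, 2 rose and 5 fell (3 and 6 adjusted over the list alone), with DUSP6 (-0.87 ± 0.10) and IER3 (-0.68 ± 0.10) lower and JUNB (0.74 ± 0.11) higher, and without treated wild type replicate 1 or 3, or untreated replicate 1, 3 fell, and without untreated replicate 3 or any 1 treated library, 1 rose. Of 24 TGF-beta and YAP targets, 3 rose and 5 fell, with INHBA (-0.81 ± 0.08) lower and LTBP2 (0.70 ± 0.12) higher. Without treated wild type replicate 1 or 3, 2 of them fell, without untreated replicate 1 or 2, 3 fell, and without untreated replicate 3, 7 fell.

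Genes of the keratinocyte itself went both ways. Of 25 differentiation genes, 3 rose and 2 fell, with the protease gene KLK5 (0.68 ± 0.10) higher and the transcription factor genes PRDM1 (-1.20 ± 0.19) and EHF (-0.44 ± 0.09) lower. Without untreated wild type replicate 3, which stood apart, 6 fell. Of 21 basal and hemidesmosome genes, 4 rose and 4 fell (5 and 5 adjusted over the list alone), with CAV1 (-0.50 ± 0.07), COL17A1 (-0.46 ± 0.08) and TP63 (-0.53 ± 0.11) lower and DLL1 (0.50 ± 0.10) higher. Among 9 simple epithelial and activation keratins only KRT86 fell (-0.64 ± 0.17), while 3 fell without untreated wild type replicate 3 and 0 without untreated replicate 1 or treated replicate 1 or 3. Of 15 lipid barrier genes 1 rose and 2 fell, and 1 fell without untreated wild type replicate 3 or treated replicate 1 or 3, while 2 rose without untreated replicate 2 and 0 without treated replicate 3. Of 13 antimicrobial genes 1 rose and 2 fell (1 and 1 adjusted over the list alone), with S100A9 lower (-0.60 ± 0.17), and 0 fell without treated replicate 2 and 1 without any other wild type library. Of the antimicrobial list 2 rose without untreated replicate 1 and 0 without any 1 treated library. Of 30 S phase genes 2 rose and 8 fell (2 and 9 adjusted over the list alone), with POLA1 lower (-0.42 ± 0.08), and without treated wild type replicate 2 or 3, 5 and 3 fell, and without untreated replicate 3, 4 rose. Of 30 G2/M genes 1 rose and 5 fell (1 and 4 adjusted over the list alone), with CCNB2 (-0.59 ± 0.10) and CDK1 (-0.49 ± 0.09) lower. Without untreated wild type replicate 3, or any 1 treated library, 3 of those fell, and without untreated replicate 1, 2 rose. Of 22 hypoxia and glycolysis genes none rose and 4 fell, with ADM lower (-0.57 ± 0.10), and without untreated replicate 3, 7 fell, and without untreated replicate 1, 1 rose. Of 25 cholesterol synthesis genes 3 rose and 2 fell, with EBP higher (0.63 ± 0.12), and 1 fell without treated replicate 1 or 2 and 4 without untreated replicate 2. Of 15 Wnt genes 1 rose and 3 fell (2 and 4 adjusted over the list alone), with BAMBI lower (-0.75 ± 0.12), and without untreated replicate 3, 5 fell, and without untreated replicate 1 or any 1 treated library, 0 rose. Of 20 p53 targets SERPINB5 (-0.74 ± 0.07) and CDKN1A (-0.42 ± 0.10) fell and none rose, but 1 rose without untreated replicate 1. Of 6 hedgehog genes SMO had the smallest adjusted p (0.24 ± 0.10, adjusted p = 0.0868, edgeR quasi-likelihood), and DESeq2 called 0 of them as well, while 1 rose without untreated or treated replicate 2. Among 5 measured markers of other cell types, CDH5 (0.82 ± 0.21) and CD68 (0.58 ± 0.16) rose, and without untreated wild type replicate 3 CD68 had adjusted p = 0.0577, and without treated replicate 2, 1 of that list rose. Of 27 known regulatory lncRNAs 4 rose and 4 fell, with LINC00657, now NORAD (0.61 ± 0.09), and UCA1 (0.57 ± 0.13) higher and ZFAS1 lower (-0.35 ± 0.07), and without treated wild type replicate 1, 2 or 3, 2, 2 and 1 fell.

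**Figure D3:**
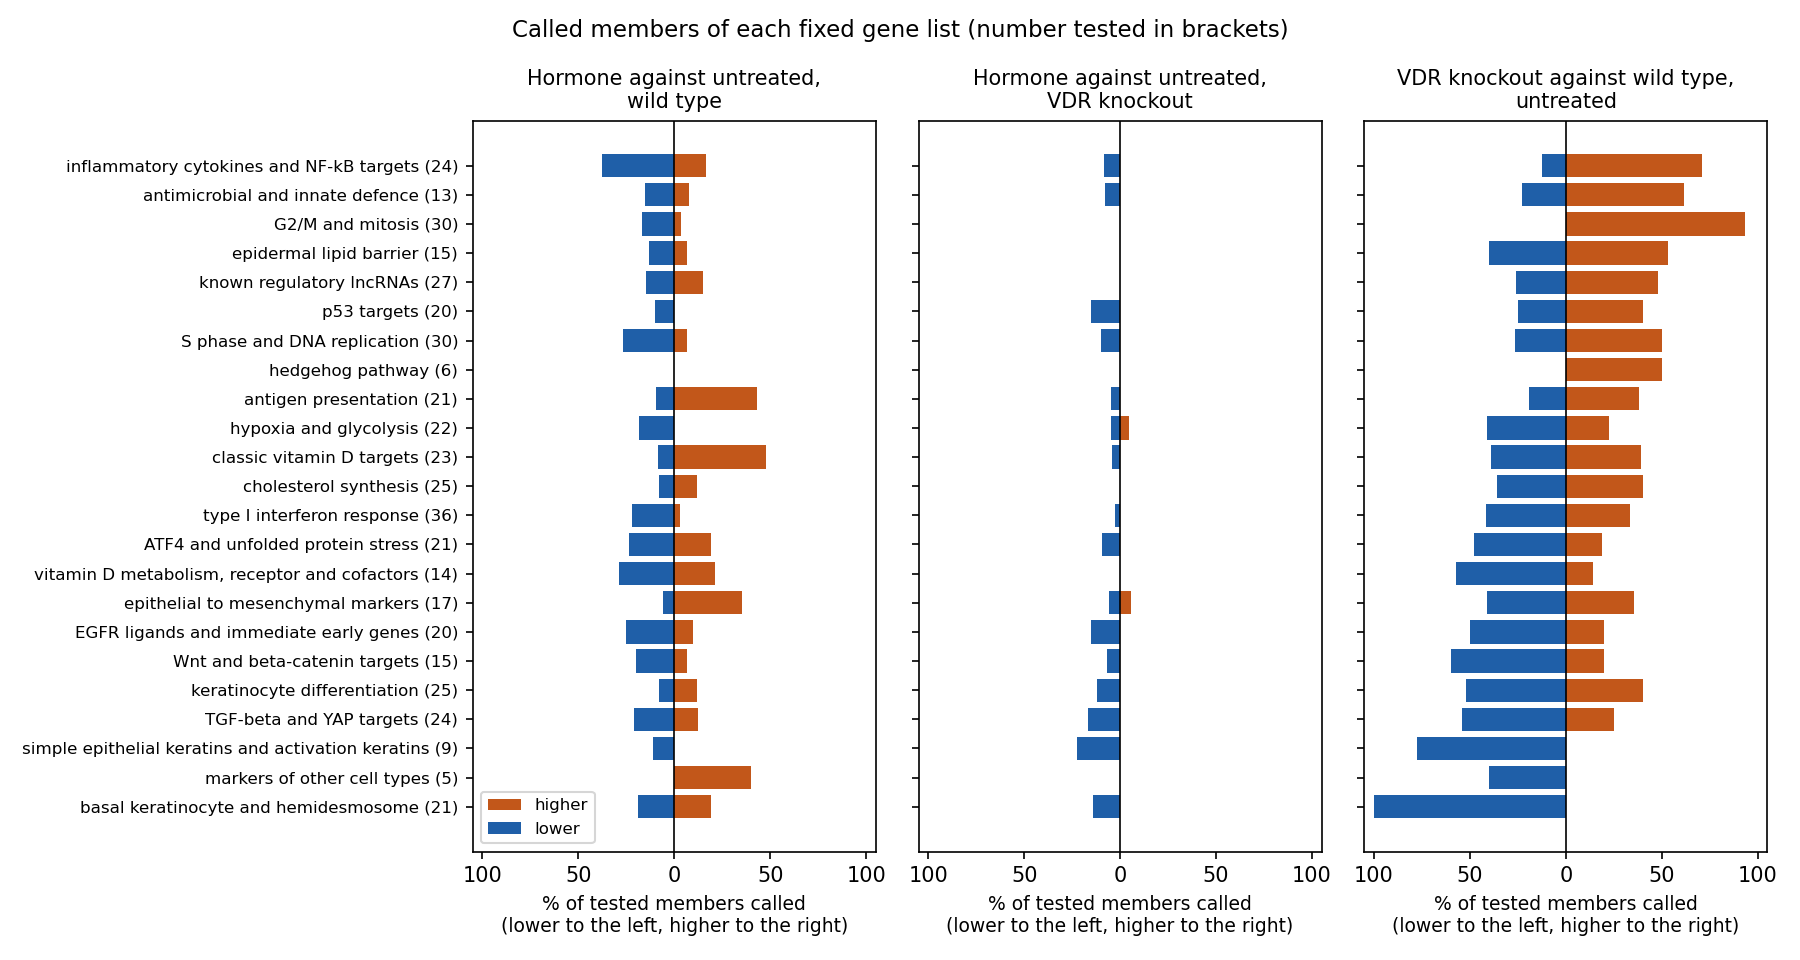
Share of the tested members of each fixed list (number in brackets) called higher (to the right) or lower (to the left), in %, for the hormone in wild type cells, the hormone in knockout cells, and knockout against wild type untreated. In the last comparison all 21 basal and hemidesmosome genes were lower and 28 of 30 G2/M genes higher.

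The authors' own deposited enrichment tables for this comparison held 54 gene ontology terms for genes higher with treatment and 74 for genes lower. Of these, 36 and 49 had an authors' adjusted p below 0.05. Among the higher genes, endoplasmic reticulum lumen held 46 of 896 listed genes (the authors' adjusted p = 6.62e-12) and serine-type peptidase activity 31 of 862 (7.60e-11). Among the lower genes, nucleosome held 24 of 859 listed genes (4.13e-12) and ribosome 46 of 859 (2.88e-08).

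The question of the series title, which lncRNA genes the hormone raised, was taken up by gene type. Of 1491 lncRNA genes tested, 135 rose and 85 fell with treatment in wild type cells (edgeR quasi-likelihood, adjusted p below 0.05), with median log2 fold changes of 0.52 and -0.48. These were 9.05% and 5.70% of lncRNA genes, against 11.8% and 13.9% of other genes. CTC-523E23.11, now LINC03049 (chromosome 19, 34849278 to 34860576, GRCh38), had no count in untreated wild type cells and 32, 40 and 40 counts in the treated libraries, 2.88 CPM on average. It was at least 33.0-fold higher, taking 3 counts over the untreated group as the floor, which covers counting error only (adjusted p = 3.76e-06). Its nearest counted gene lies 62.7 kb away. RP11-510J16.5, now HSD17B2-AS1 (chromosome 16, 82044336 to 82139631), rose from 0.146 to 2.29 CPM (log2 fold change 3.89 ± 0.39, adjusted p = 7.58e-06). AP001053.11, now AATBC (chromosome 21, 43805758 to 43812567), rose from 0.439 to 2.04 CPM (2.20 ± 0.30, adjusted p = 0.000134). Other rises with small adjusted p were in the host gene of SCARNA17 (1.17 ± 0.12), SCARNA2 (1.17 ± 0.14), LINC00657 (0.61 ± 0.09), TERC, the RNA of telomerase (0.87 ± 0.12), and FLG-AS1 (0.71 ± 0.11), which overlaps FLG. The counts of the SCARNA17 host, SCARNA2 and TERC each equal those of another gene ID, so their reads have more than 1 possible origin. Falls were in RP11-626H12.1 (-0.84 ± 0.08), AC058791.1 (-1.03 ± 0.13), the hsa-mir-146a host gene (-0.72 ± 0.10), RP6-99M1.2, which holds MIR221 and MIR222 (-0.94 ± 0.13), LINC00472 (-0.45 ± 0.07), SNHG5 (-0.49 ± 0.08), RP13-631K18.5 (-0.76 ± 0.12) and AC002066.1 (-0.47 ± 0.08), which overlaps CAV2. Of the lncRNA genes called, 89 of the 135 higher and 45 of the 85 lower overlap another counted gene, and the strand used in counting is not given in the sources used here. Without treated wild type replicate 3, 88 rose and 42 fell, and without treated replicate 1, 55 fell.

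The same treatment was compared in the cells labelled as knockout, in which VDR RNA is still counted. KRT14, the main basal keratin gene, fell from 107.2 ± 3.22 to 58.6 ± 2.18 CPM (log2 fold change -0.87 ± 0.10, adjusted p = 0.00169), with KRT15 (-0.66 ± 0.11), KRT5 (-0.48 ± 0.12) and KRT6A (-0.68 ± 0.10). HOXC-AS1 (-1.52 ± 0.29), TNFSF12 (-1.17 ± 0.29), whose counts equal those of its readthrough gene, TMEM125 (-1.15 ± 0.27), the Wnt receptor gene FZD7 (-0.84 ± 0.19), FAM43A (-0.84 ± 0.17) and S100A8 (-0.82 ± 0.21) fell too, as did 1 of the gene IDs of HLA-DMB (-0.86 ± 0.17). The genes of the rule that rose included small noncoding RNA genes, namely SNORD11 (1.55 ± 0.34), SNORD35A (1.04 ± 0.23), SNORD32A (1.01 ± 0.23) and SNORD33 with SNORD34 (0.98 ± 0.24 each, with equal counts), and at copies of snoU13 (2.03 ± 0.50) and Y_RNA (1.11 ± 0.28). CR848007.2 (1.81 ± 0.43), CTD-3051D23.4 (1.02 ± 0.26) and TSACC (0.98 ± 0.23) also rose. Of 146 snoRNA genes, a group chosen after the values were seen, 7 rose and 2 fell, and 0 were called in edgeR quasi-likelihood without untreated knockout replicate 1 or 3 or treated replicate 2 or 3. In all, 134 genes rose and 240 fell (edgeR quasi-likelihood, adjusted p below 0.05), 7 and 4 of them at least 2-fold. With library size alone as the scaling, the share of called genes that rose was 20% instead of 35.8%.

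These counts moved with single libraries. Without treated knockout replicate 1, 2 or 3, 29, 1 and 13 genes rose and 65, 8 and 50 fell. Without untreated knockout replicate 1, 0 genes rose in edgeR quasi-likelihood and 14 fell. Without replicate 2, 66 rose and 212 fell, and without replicate 3, 59 rose and 78 fell. In the full data 3128 genes had an unadjusted p below 0.05, and DESeq2 called 411 higher and 500 lower. Without untreated wild type replicate 3, which this comparison uses only for its estimate of spread, 1025 genes rose and 1340 fell, and all 374 were called again.

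By list, 3 of 20 EGFR ligands and immediate early genes fell and none rose (7 and none adjusted over the list alone), namely PHLDA1 (-0.56 ± 0.08), JUN (-0.59 ± 0.10) and JUNB (-0.59 ± 0.11). Of 24 TGF-beta and YAP targets 4 fell (6 adjusted over the list alone), namely ID1 (-0.62 ± 0.08), ID3 (-0.62 ± 0.09), ID2 (-0.57 ± 0.12) and CYR61 (-0.76 ± 0.13). KRT6A and KRT19 (-0.55 ± 0.09) fell among 9 simple epithelial and activation keratins (5 adjusted over the list alone). DDIT4 (-0.60 ± 0.10) and ASNS (-0.51 ± 0.11) fell among 21 ATF4 genes (1 rose and 5 fell adjusted over the list alone). These 4 lists stood lower by camera (adjusted p = 0.000141, 0.0101, 0.000873 and 0.00169), and none did with an estimated correlation (adjusted p = 0.111 for the EGFR list and 0.263 for the others). Camera also called lower the lists of antigen presentation (adjusted p = 0.00407), differentiation (0.0101), NF-kB targets (0.0217), classic vitamin D targets (0.0354), Wnt (0.0358) and hypoxia (0.0358), each with adjusted p = 0.263 with an estimated correlation. Few of their members passed: 1 antigen presentation gene fell, 3 differentiation genes, including KRT13 (-0.79 ± 0.16), 2 NF-kB targets, including CXCL1 (-0.60 ± 0.10), and 1 each of the classic targets (CDKN1A, -0.61 ± 0.10) and the Wnt list (DKK1, -0.52 ± 0.09). Of the hypoxia list ADM fell (-0.81 ± 0.10) and P4HA1 rose (0.32 ± 0.08). In the same order those adjusted over the list alone were 3, 5, 6, 7, 2 and 5 lower and 0, 1, 1, 3, 0 and 1 higher, and without untreated wild type replicate 3, 6, 5, 6, 7, 4 and 7 fell and 0, 1, 1, 3, 0 and 1 rose. With a knockout library left out, 0 to 1, 0 to 4, 0 to 2, 0 to 3, 0 to 1 and 1 to 2 fell, the lowest each time without treated replicate 2, and 0 rose. Without treated knockout replicate 3, camera no longer called classic targets or differentiation (adjusted p = 0.0594 each), Wnt (0.0826) or hypoxia (0.0889). Without untreated replicate 2 it did not call NF-kB targets (0.0812), Wnt (0.159) or hypoxia (0.0512), and without untreated replicate 3, hypoxia (0.0543). Without treated knockout replicate 2, 0 of the EGFR list passed in edgeR quasi-likelihood and 1 of the TGF-beta list, and without untreated wild type replicate 3 these were 6 each. Without untreated knockout replicate 1 or treated replicate 2, 1 of the keratins and 0 of the ATF4 list passed. Without untreated replicate 1, 2 of the TGF-beta list fell, and without treated replicate 3, 1 of the keratins, while 1 of the ATF4 list fell without untreated replicate 3 or treated replicate 1 or 3. Without untreated wild type replicate 3, 4 keratins fell, and 9 of the ATF4 list fell and 1 rose. The deposited tables held 173 terms for genes lower with treatment in knockout cells, 133 of them with an authors' adjusted p below 0.05. Among them were epithelial cell differentiation with 32 of 306 listed genes (the authors' adjusted p = 0.000211) and cellular response to tumor necrosis factor with 20 of 306 (0.000511). Of the matched genes listed in these terms, 49.2% were called here.

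Whether the response differed between genotypes was tested directly as the difference of the responses. CYP24A1 had the largest difference that does not rest on counts near 0 (log2 difference -5.60 ± 0.21, adjusted p = 1.66e-09). RP11-510J16.5, which had few counts in untreated wild type cells, also passed (-3.97 ± 0.49, adjusted p = 7.18e-05). In knockout cells it stood at 1.55 CPM untreated, above its untreated wild type level, and at 1.47 CPM treated. CTC-523E23.11 was at 0.15 and 0.238 CPM in knockout cells, and its difference passed (adjusted p = 0.000608). FER1L4 (adjusted p = 0.0233) and CTB-11I22.2 (adjusted p = 0.0128) also passed with a lower response in knockout cells, from 1 and 3 counts in the untreated wild type group. The sign of a difference, knockout minus wild type, does not give the size of the response in either genotype. Among the classic vitamin D targets, 11 of 23 had a called difference below 0 and 2 above 0 (13 and 2 adjusted over the list alone). They included DUSP10, SERPINB1 (-1.35 ± 0.17) and CLMN (-0.80 ± 0.10). The list differed from other genes (camera adjusted p = 7.84e-06, and adjusted p = 0.0113 with an estimated correlation). With any 1 library left out except untreated wild type replicate 1, 0 or 1 of these 23 had a called difference above 0 in edgeR quasi-likelihood. Of 21 antigen presentation genes 12 had a called difference below 0 and 2 above 0 (12 and 3 adjusted over the list alone), including TAPBP (-0.77 ± 0.12) and HLA-C (-1.29 ± 0.24). Camera called this list (adjusted p = 0.00261), but not with an estimated correlation (adjusted p = 0.86). INHBA (0.97 ± 0.11), ANKRD1 (1.87 ± 0.29) and IL1B (1.22 ± 0.18), which fell in wild type cells, responded higher in knockout cells.

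Over all genes the response was higher in knockout cells for 2025 genes and lower for 1832 (edgeR quasi-likelihood, adjusted p below 0.05), 162 and 227 of them by at least 2-fold. The log2 difference rose with gene span (Spearman's rho 0.358 across genes). For the treatment response itself rho with span was -0.234 in wild type and 0.4 in knockout cells. After removal of this trend 3247 genes were called, 2557 of them among the 3857 called before. Of the 3602 genes called in wild type cells, 2799 (77.7%) had a called difference, against 26.3% of all genes tested. The wild type fold change that picked these genes also enters the difference, so a high share follows in part from the choice. The 72 genes that rose at least 2-fold in wild type cells had a median log2 fold change of 1.28 there and -0.08 in knockout cells, and the 62 that fell had -1.23 and 0.13. Of 208 genes called in both genotypes, 28 went the same way. Both rose for 3 genes, where 15.4 would be shared if the calls were independent, and both fell for 25, where 31.3 would be. Without untreated wild type replicate 3 the shared falls exceeded that number (257 against 163), as they did after removal of a trend with gene span (26 against 16.3), while shared rises stayed below it (26 against 111.5, and 0 against 5.6). Spearman's rho between the responses was -0.374 across genes, which are not independent replicates. It was -0.237 without untreated wild type replicate 3 and -0.293 after removal of the span trend. The genes with the largest differences above 0, RNU1-7, GTF2IRD2 and HIST2H4A, varied between libraries of 1 group by far more than other genes. For RNU1-7 the untreated wild type libraries had 15, 21029 and 16641 counts.

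**Figure D4:**
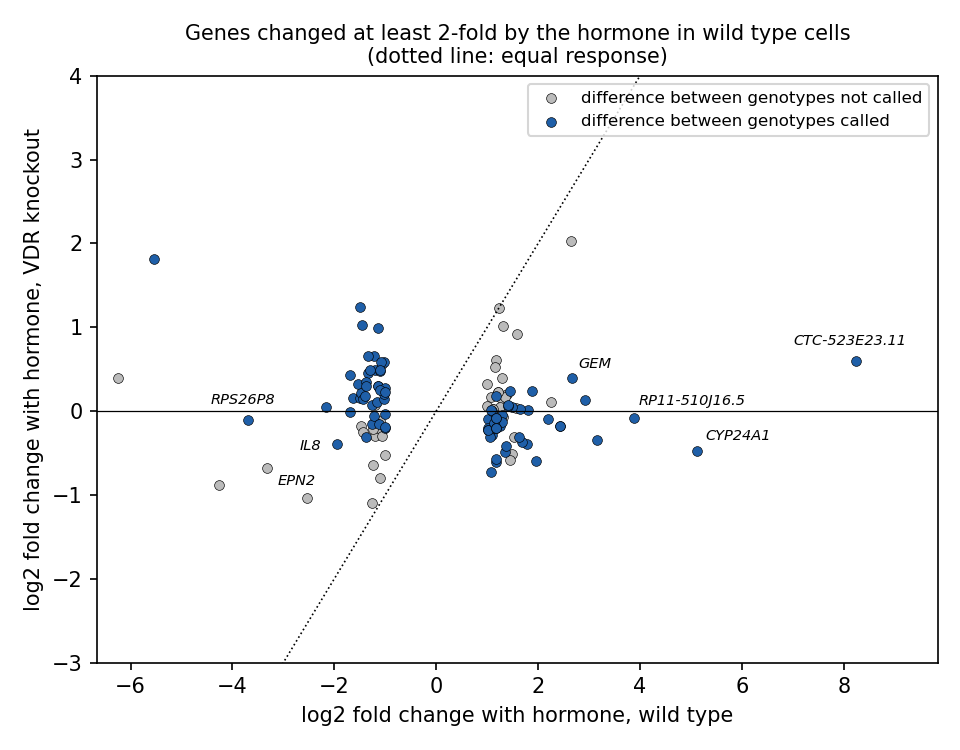
Fitted log2 fold change with hormone in knockout (vertical) against wild type cells (horizontal) for the 134 genes changed at least 2-fold in wild type cells, coloured by whether the difference between genotypes was called (88 genes) or not. The fitted value of CTC-523E23.11 depends on the prior count because its untreated group is at 0, and the dotted line marks an equal response.

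Knockout and wild type cells were next compared without added hormone. TRIM31, a ubiquitin ligase gene, was at 128.7 ± 18.8 CPM in knockout and 2.47 ± 1.13 CPM in wild type cells (log2 fold change 5.68 ± 0.20, adjusted p = 5.91e-11). Among genes at or near 0 in wild type cells, RP11-91K9.1 was at least 25.0-fold higher and TLR1 with TLR6, innate receptor genes with equal counts, at least 17.9-fold. CYP26A1, which encodes an enzyme that clears retinoic acid, was 71.0-fold higher (95% counting interval 12.4 to 2834, from 1 count in wild type cells), FER1L4 86.9-fold (15.3 to 3461), FBXO43 50.6-fold (8.78 to 2029) and RP11-180O5.2 42.8-fold (14.4 to 209.7). TAGLN, an actin-binding protein gene of contractile cells, was at 0.130 against 19.8 ± 5.48 CPM (-7.13 ± 0.32, adjusted p = 2.14e-11). GJB6, a connexin gene, had no count in knockout cells and was at least 61.1-fold lower. DIAPH2 (-6.01 ± 0.30), SHANK2 (-5.24 ± 0.20) and 1 of the gene IDs of ZNF585B (-5.03 ± 0.44) were lower, and so were WNK2 (225.0-fold, interval 39.9 to 8940) and the cornified envelope gene SPRR2D (178.7-fold, interval 49.0 to 1483). HIST2H3DP1 and a copy of U2 higher, and RNU1-7, ASMTL and GTF2IRD2 lower, met the rule as well, but these have copies elsewhere in the genome or vary between libraries of 1 group by far more than the rest. Of 14676 genes, 5207 were higher and 5019 lower (edgeR quasi-likelihood, adjusted p below 0.05), 1464 and 1376 of them at least 2-fold. Scaling by library size alone put the median log2 fold change of all genes at 0.13, and 60.4% instead of 50.9% of called genes were then higher.

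All 21 basal keratinocyte and hemidesmosome genes were lower in untreated knockout cells, including ITGB4 (-1.93 ± 0.09), PLEC (-2.33 ± 0.11) and COL7A1 (-2.11 ± 0.10), parts of the attachment to the basement membrane. The list stood lower than other genes (camera adjusted p = 6.05e-10, but adjusted p = 0.0781 with an estimated correlation). Of 30 G2/M genes 28 were higher and none lower (29 and none adjusted over the list alone), including the kinesin gene KIF11, the phosphatase gene CDC25C (1.57 ± 0.10), CDK1 (1.24 ± 0.08) and NEK2 (1.08 ± 0.07), and this list passed with both correlations (camera adjusted p = 6.05e-10, and adjusted p = 0.0277 with an estimated correlation). Of 9 simple epithelial and activation keratins 7 were lower, including KRT6A (-2.25 ± 0.10) and KRT17 (-3.23 ± 0.17), with camera adjusted p = 0.00584, and adjusted p = 0.454 with an estimated correlation. Of 24 inflammatory cytokines and NF-kB targets 17 were higher and 3 lower, including TNFAIP2 (2.24 ± 0.08), NFKBIA (1.67 ± 0.07), IL18 (1.51 ± 0.07) and BIRC3 (1.25 ± 0.08), with camera adjusted p = 0.00171, and adjusted p = 0.207 with an estimated correlation. The other lists did not pass camera. Of 25 differentiation genes 10 were higher, among them the transcription factor genes GRHL3 (3.61 ± 0.15), EHF (1.85 ± 0.09) and ELF3 (2.76 ± 0.15), and 13 lower. Of 24 TGF-beta and YAP targets 6 were higher and 13 lower, including THBS1 (-2.12 ± 0.12). Of 20 EGFR ligands and immediate early genes 4 were higher and 10 lower, including FOSL1 (-2.45 ± 0.11) and EGFR (-1.37 ± 0.08). Of 15 Wnt genes 3 were higher and 9 lower, including WNT7A (-2.35 ± 0.09) and DKK1. Of the classic vitamin D targets 9 were higher, including DUSP10 (2.83 ± 0.09), and 9 lower, including CYP24A1 (adjusted p = 3.29e-07). Of 1491 lncRNA genes 801 were higher and 236 lower. The deposited tables held 59 terms for genes higher, among them chromosome segregation with 128 of 3062 listed genes (the authors' adjusted p = 4.65e-05), and 212 for genes lower, among them anchoring junction with 219 of 3548 (5.32e-13) and ribosome biogenesis with 162 of 3405 (2.77e-10). Of the 59 and 212 terms, 51 and 142 had an authors' adjusted p below 0.05.

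The genotypes were also compared in treated cells. In both this comparison and the untreated one 8711 genes were called, where 7757 would be shared if the calls were independent, and 8428 of them had the same direction, and rho between the fold changes was 0.854 across genes. TRIM31 (6.25 ± 0.22) stayed higher, RP11-91K9.1 was 96.8-fold higher (95% counting interval 17.0 to 3865) and RP11-180O5.2 142.7-fold (25.2 to 5677), and TXK, a kinase gene, and TM4SF1-AS1 were at least 14.3-fold and at least 13.2-fold higher. CYP24A1 was lower (log2 fold change -7.10 ± 0.17, adjusted p = 6.61e-13). GJB6 was at least 56.1-fold lower, TAGLN 562.1-fold (100.5 to 22240), SHANK2 lower (-5.49 ± 0.22), and the protease gene MMP10 50-fold lower (13.5 to 418.7). DIAPH2 (160.4-fold, 44.1 to 1330), WNK2 (143.2-fold, 39.3 to 1188), SPRR2D (100.1-fold, 27.4 to 831.8) and IGFL1 (79.5-fold, 13.9 to 3177) were lower too. U2, HIST2H4A, HIST2H2AA4, HIST2H3A and CR848007.2 higher, and ARHGEF5 lower, met the rule with the same doubt over copies. In all, 5640 genes were higher and 5493 lower (edgeR quasi-likelihood, adjusted p below 0.05), 1922 and 2034 at least 2-fold. Library size alone as the scaling put the median at 0.13 and made 56.8% instead of 50.7% of called genes higher.

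The lists called untreated kept their directions in treated cells. Of the basal and hemidesmosome genes 18 of 21 were lower, including PLEC (-2.75 ± 0.11), with camera adjusted p = 1.21e-07, and adjusted p = 0.155 with an estimated correlation. Of the G2/M genes 26 of 30 were higher, including CDK1 (1.70 ± 0.09), with camera adjusted p = 1.21e-07, and adjusted p = 0.067 with an estimated correlation. Of the activation and simple epithelial keratins 7 of 9 were lower, including KRT6A (-2.72 ± 0.10), with camera adjusted p = 0.00458, and adjusted p = 0.368 with an estimated correlation. Of the NF-kB targets 18 of 24 were higher and 4 lower, including CCL2 (2.32 ± 0.12), with camera adjusted p = 0.0043, and adjusted p = 0.273 with an estimated correlation. Of the classic vitamin D targets 14 of 23 were lower, among them THBD, a gene of the clotting system (-2.52 ± 0.15), and 7 higher. The deposited tables held 148 terms for genes lower, among them cornification with 41 of 4413 listed genes (the authors' adjusted p = 7.49e-05), and 59 for genes higher, among them chromosome segregation with 165 of 3915 (2.37e-07). Of the 148 and 59 terms, 91 and 46 had an authors' adjusted p below 0.05.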

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

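The tests named here were written before their results were seen, except that of sequencing depth on untreated wild type replicate 3, which was chosen only after the result was seen, as were the bootstrap interval and the values of the other libraries given with this pattern. The response to the hormone differed between wild type and knockout cells, by a test of the difference itself, for 3857 genes. After removal of a trend with gene span 2557 of them were still called. Of 100 splits drawn, the real one included, 1 had as many genes, the real one, and the highest other had 1812. The splits exchanged treatment labels within each genotype, which removes the response itself. They set the count against no response in either genotype, so they cannot test whether the responses were equal. VDR (log2 difference 0.636) and CYP24A1 (-5.598) are among the 3857 genes. For RP11-510J16.5 the difference was -3.973, for CTC-523E23.11 -7.648, for FER1L4 -3.505 and for CTB-11I22.2 -2.782. The differences of RNU1-7 (20.222), GTF2IRD2 (16.457) and HIST2H4A (12.955) rest on 1 to 3 libraries with high counts of genes that have copies elsewhere. CR848007.2 (7.35) and TXK (4.966) had no count in treated wild type cells, and TXK had adjusted p = 0.0986 without untreated wild type replicate 3. Fitted differences of genes with a group at 0 to 3 counts depend on the prior count.

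On the first component untreated wild type replicate 3 lay between its group and the knockout libraries. On the second it was at -32.4, below all other libraries, while knockout libraries lay at -11.8 to 16.9. Whether a mixture with knockout RNA could give that score was not tested. Over 81 genes at least 8-fold higher and 63 at least 8-fold lower in knockout cells, replicate 3 had gone a median share of 0.044 and 0.217 of the way to the knockout level. A mixture with knockout RNA would put these medians within 0.1 of each other and the interquartile range of the shares in the higher genes below 0.15. The gap was 0.173 (bootstrap 95% interval over genes 0.046 to 0.312) and the range 0.088. As first written, a gap above 0.1 was to go against a mixture, and 0.173 met that. The interval, added later, reaches below 0.1, so a mixture stays open. In the lower genes the range was 0.554, and it was 0.425 and 0.498 in the other libraries of the group. The reference mean for those libraries held replicate 3 itself, so they are no independent yardstick. The range in the lower genes thus decides nothing about a mixture. A different state of this culture was to give a range above 0.3, and one below 0.15 was to exclude it. That bound was taken to decide nothing at shares this small. The other libraries of the group, which do not stand apart, had 0.059 and 0.069, again with replicate 3 in their reference mean. These explanations cannot be told apart here. As a description only, the deviation of this library from its group had a Spearman's rho of 0.346 with gene span across genes. In the other 11 libraries the highest such value was 0.287 in size, but replicate 3 was part of the reference for the other libraries of its group. Whether a difference tied to gene span sets this library apart was not tested. Depth is not the reason, since 12.11 M counts lie inside the range of the other libraries.

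For the 374 genes called between treated and untreated knockout cells, a trend of the fold change with gene span may account for part. Called genes that rose spanned a median of 139.2 kb, those that fell 7.9 kb, and genes tested 28.3 kb. After the trend was removed 38.8% were still called, against 95.5% with spans shuffled among genes. All 374 kept their sign, and their median absolute log2 fold change went from 0.42 (median SE 0.09) to 0.34 (0.08). By these medians most of the change was left after the removal. How near to the threshold the lost calls lay, and so why they ended, was not tested. After thinning every library to the smallest total 70.9% were still called, which leaves depth open. A response to the hormone that needs no receptor and is shared with wild type cells does not account for them as a whole, since 30.2% had the same sign there.

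For the genes that differ between untreated knockout and wild type cells, DNA copy number could explain a part at most: the median of neighbouring genes explained 7.68% of the variance, and 0% with genes shuffled over positions. Loss of receptor activity driven by hormone in the serum would lower the genes that the hormone induces in wild type cells, but 68 such genes had a median log2 fold change of 1.287, with 43 higher and 9 lower. In simulated data with unchanged knockout cells and shared controls that median was 0.22, over 132 induced genes rather than 68. CYP24A1 went the other way, at 11.56 to 21.01 CPM in untreated knockout and 46.25 to 51.3 CPM in untreated wild type libraries. Since 69.7% of all genes tested were called between these groups, other differences may mask a fall. Lost receptor activity thus does not account for these genes as a whole, but a part played by it stays open. What separates knockout from wild type cells here was not resolved, and the number of knockout clones is not given in the sources used here.

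Each comparison of 2 groups allows 10 splits of its 6 libraries, too few for a share under 0.05. Every other split mixes the 2 groups, so a difference between them, whatever its cause, adds to the spread and lowers the calls. The real split was the only 1 with as many calls in each: 3602 against a highest other of 1 for treatment in wild type cells, 374 against 4 in knockout cells, 10226 against 1 untreated and 11133 against 0 treated for genotype, and 220 against 0 for lncRNA genes with treatment.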

How the results depend on the processing

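Under the alternatives 172 gene counts stayed within a factor of 1.5 and 56 moved, 223 list tests kept their side of the threshold and 31 lost it, and for the named genes 3335 values kept their side, 265 lost it and 4 gained it. No result reversed. For treatment in wild type cells (1688 higher, 1914 lower) the counts were 1092 and 1126 with the 2 groups alone, 816 and 994 at adjusted p below 0.01, 72 and 62 at 2-fold, and 1010 to 1825 and 1102 to 1970 with a library left out. For treatment in knockout cells (134 and 240) they were 411 and 500 with DESeq2, 833 and 942 with the 2 groups alone, 37 and 106 with the replicate block, 51 and 121 after removal of the span trend, 459 and 765 without both untreated wild type replicate 3 and untreated knockout replicate 1, 7 and 4 at 2-fold, and 0 and 36 at adjusted p below 0.01. Those lower were 392 with library size alone and 369 with limma on the deposited CPM. With a library of the comparison left out they were 0 to 66 and 8 to 212. Stricter thresholds explain the direction of their own counts. For the others, the last range included, the cause was not tested. Fewer libraries do not always lower these counts. Without untreated wild type replicate 3, used here only for the estimate of spread, 1025 genes rose and 1340 fell. The genotype comparisons had 1464 and 1376 genes untreated and 1922 and 2034 treated at 2-fold. The responses that differ between genotypes were 162 higher and 227 lower in knockout cells at 2-fold, and 1047 and 874 at adjusted p below 0.01. lncRNA genes with treatment in wild type cells (135 and 85) were 85 and 54 with the 2 groups alone, 16 and 14 at 2-fold, 59 and 35 at adjusted p below 0.01, 17 and 16 when defined by symbol, which takes fewer genes, and 88 to 132 and 42 to 91 with a library left out. Replicate numbers did not pair the libraries: over 18 pairs with the same number the correlation of deviations was -0.175 to 0.121. Of the 31 list tests, 19 were lost with an estimated correlation, 2 with fry, 2 after removal of the span trend (adjusted p = 0.292 for NF-kB targets and 0.0809 for ATF4 in treated knockout cells) and 8 with a library left out.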

Other observations

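The families and regions here were chosen only after the data were seen, and no test of a hypothesis was made on them. Of 66 histone genes, 54 fell and none rose with the hormone in wild type cells (median log2 fold change -0.63), among them HIST1H4H (-0.88 ± 0.07), HIST1H2BK (-0.82 ± 0.10), HIST1H4C (-0.79 ± 0.08) and HIST1H3B (-0.68 ± 0.08), which encode proteins that package DNA. In knockout cells 1 rose and 2 fell with treatment, with 0 to 3 rising and 0 to 11 falling when a library was left out, the highest without untreated wild type replicate 3. Between untreated genotypes 61 were higher in knockout cells and none lower (median 0.79), as with HIST1H1B (1.14 ± 0.08), and the direction held under each scaling. Histone genes took 0.974 to 1.091% of counts in untreated and 0.648 to 0.7% in treated wild type libraries, and 1.855 to 1.932% and 1.74 to 1.812% in knockout libraries. Of 83 ribosomal protein genes 33 fell and none rose in wild type cells with treatment. With untreated wild type replicate 1 or 3 left out, 20 and 53 fell, with treated replicate 1, 2 or 3 left out, 20, 21 and 19, and after removal of the trend with gene span 55. In untreated knockout cells 60 were lower than in wild type cells, among them RPL13A (-1.06 ± 0.11) and RPS23 (-0.90 ± 0.13), and 4 were higher, and with library size alone as the scaling 48 were lower and 12 higher. Those higher were 7 without untreated knockout replicate 1 and 8 after removal of the span trend. Of 146 snoRNA genes 2 rose and 31 fell in wild type cells with treatment (median -0.22). Without treated wild type replicate 1, 2 or 3, 0, 0 and 1 rose and 20, 20 and 16 fell, and after removal of the trend with gene span 6 rose and 16 fell (median -0.09). In knockout cells 7 rose and 2 fell (median 0.20), and 0 were called in edgeR quasi-likelihood without untreated knockout replicate 1 or 3 or treated replicate 2 or 3. DESeq2 called 8 higher and 3 lower, and without untreated wild type replicate 3, 18 rose and 10 fell. The response was higher in knockout cells for 41 and lower for 2, and after removal of the span trend for 25 and 10.

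Genes at several chromosome ends were lower together in untreated knockout than in wild type cells, by their GRCh38 positions. Each region is a run of at least 30 genes. Its genes are those whose neighbours, up to 50 on each side, had a median log2 fold change at least 0.5 in size. The shared direction within a region thus follows from the choice. Of all 14676 genes tested 5019 were lower. On chromosome 8 at 141.2 to 145.1 Mb 66 of 80 genes were lower and 5 higher (median -0.85), and on chromosome 19 at 0.3 to 6.0 Mb 106 of 140 were lower and 10 higher (median -0.74). On chromosome 9 at 133.4 to 138.2 Mb 66 of 83 were lower and 3 higher (median -0.73), and on chromosome 1 from its start to 3.7 Mb 51 of 70 were lower and 6 higher (median -0.75). Runs at an end of chromosomes 16 (53 of 75 lower, 6 higher), 17 (36 of 53 lower, 7 higher) and 22 (31 of 40 lower, 2 higher) were lower too. The region of chromosome 6 at 25.1 to 28.4 Mb, which holds the main histone gene cluster, had 49 of 55 genes higher and none lower (median 0.79).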
